A study of Mus musculus with 6 samples.

How the data were processed

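The series holds 6 arrays of total RNA from mouse keratinocyte lines, 2 each of a wild-type line, an α3-null line and the null line rescued with human α3. Groups and replicate numbers were taken from the sample titles. The design text calls the arrays biological replicates, and nothing in the sources used here says whether the 2 arrays of a line came from separate cultures, so p-values measure the spread between these arrays, within 1 line of each kind.

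Per the labels, the deposited values are PLIER intensity values from an analysis of core exons on Affymetrix Mouse Exon 1.0 ST arrays, made in Affymetrix Expression Console per the submitters' processing notes, while the design text names the Exon Array Computational Tool. PLIER summarises the probes of a transcript cluster, a set of exons assigned to the same locus, into 1 value per array. The background correction, the normalization between arrays, the software versions and the genome build are not given in the sources used here. The table had 23332 transcript clusters on 6 arrays, with no detection p-values, and the range of the values showed a linear scale. Median intensity per array was 96.6 to 108, and 10.1% to 10.7% of clusters per array lay below the pseudocount of 16.

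Gene names came from the platform annotation, with 14996 clusters assigned to 1 gene symbol (14860 distinct symbols), 1019 to several and 7317 to none in the tables used here. Symbols were updated by Entrez identifier against the RefSeq gene table of assembly GRCm38.p6, where 14941 of the 14996 matched and 0 symbols changed. No gene was named from a cluster with several symbols. Clusters without a symbol stayed in the tests, since no column marks controls; 6577 of them lie in a separate lower range of identifiers, and 370, 569 and 547 of these were among the calls in null minus wild type, rescue minus null and rescue minus wild type. The assembly table served only for names and for the order of genes, since the build behind the array annotation is not given in the sources used here. Where a symbol had several clusters (135 symbols), gene lists used the cluster with the highest mean.

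Values were analysed as log2(intensity + 16) without further normalization or filter. A difference on this scale understates the change of dim genes. A model with 1 mean per line was fitted to all 6 arrays with limma 3.58.1 (R 4.3.3; lmFit, then eBayes with an intensity trend), which left 3 residual degrees of freedom beside 3.00 prior degrees of freedom. Moderated tests were two-sided, with Benjamini-Hochberg adjustment over all 23332 clusters within each of 3 comparisons, and a cluster was called at an adjusted p under 0.05. A cluster was counted as restored when called in null minus wild type and, with the opposite sign, in rescue minus null, and as not restored when called with the same sign in null minus wild type and rescue minus wild type. For each pair of comparisons that share arrays, 100 data sets without any effect were simulated.

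Before the data were examined, 36 gene lists were written down from textbook knowledge of keratinocytes and integrins, including markers of fibroblasts, endothelium, immune cells and melanocytes. They hold 1070 entries, of which 844 were measured. The 34 lists with 5 or more measured genes were tested with limma's camera (correlation between genes preset to 0.01, Benjamini-Hochberg over 34 lists). The camera test passed 13, 9 and 4 lists in null minus wild type, rescue minus null and rescue minus wild type; with a correlation estimated for each list, 0 passed in every comparison, and with fry, which tests a list by itself, 27, 17 and 16 passed. Members were also counted as called over all clusters and adjusted over the list alone.

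Genes named in the text followed a rule written before the data were examined. It took Itga3, the 10 largest rises and 10 largest falls among called clusters with 1 symbol and non-overlapping lines (skipping predicted genes), the same for the restored and not restored sets by the smaller of their 2 differences, up to 4 genes with the smallest adjusted p of each list described, and the genes reported for α3β1. Alternatives fixed in advance were other pseudocounts, quantile normalization, median centring, filters on dim clusters, other variance models, fits of only the 2 lines compared, replicate number as a block, leaving out each array, only clusters with 1 symbol, a 2-fold threshold, and other list tests.

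The procedure was tested on simulated data with 23332 clusters. In null minus wild type it recovered 16%, 66%, 100% and 100% of 50 changed clusters each at log2 changes of 0.5, 1, 2 and 3, with 5 false among 146 calls; for rescue minus null the shares were 14%, 66%, 100% and 100%, with 8 false among 148. In null minus wild type a list shifted by -0.4 was found and 0 others of 34 were called. Clusters were drawn independently, so this does not measure false list calls where genes vary together. In the data the estimated correlation reached 0.36 (protease inhibitors). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.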

Results

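Gene expression was measured in 3 lines of immortalized mouse keratinocytes, the epithelial cells of the epidermis, that differed in integrin α3β1, a receptor through which these cells attach to laminin in the basement membrane. The wild-type line (MK116) and the α3-null line (MK546) came from different newborn mice and were immortalized with the SV40 large T antigen, a viral protein that binds p53 and Rb. The rescue line was made from the α3-null line by stable transfection of human α3. Each line was profiled on 2 exon arrays (6 arrays in all), described as biological replicates, and values below are means ± SD (n = 2) in PLIER intensity unless a log2 difference is named. Log2 differences are on the log2(intensity + 16) scale, which understates changes of dim genes. All lines were grown in a low-calcium medium that contained interferon-γ, per the labels' protocols. Median intensity per array lay between 96.6 and 108, total intensity between 12503410 and 13475844, and Pearson's r between arrays across transcript clusters was 0.990 to 0.991 within lines, 0.969 to 0.971 between wild type and null, 0.966 to 0.968 between wild type and rescue, and 0.976 to 0.977 between null and rescue. With 2 arrays per line, the number of arrays limits the precision of every value.

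The targeted gene was examined first. Itga3, which encodes the α3 subunit (transcript cluster 6791017), gave 6364 and 6287 on the wild-type arrays, 997 and 907 on the null arrays, and 1218 and 1221 on the rescue arrays. The null line thus retained 15.0% of the wild-type signal, a level at the 83.9th percentile of all clusters on these arrays, and the rescue line 19.3%. The log2 difference (± SE) was -2.71 ± 0.07 between null and wild type (limma adjusted p = 1.43e-05) and 0.35 ± 0.07 between rescue and null (limma adjusted p = 0.0219). That second call ended with quantile normalization (limma adjusted p = 0.0540), with median centring (0.0740), without the variance trend (0.0682), with only null and rescue arrays in the fit (0.0623) and in 5 of 6 fits that left an array out. The rescue construct is a human cDNA, which mouse probes may read only in part, and a cluster averages probes over the whole gene, so the null and rescue values check the labels only in part.

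**Figure D1:**
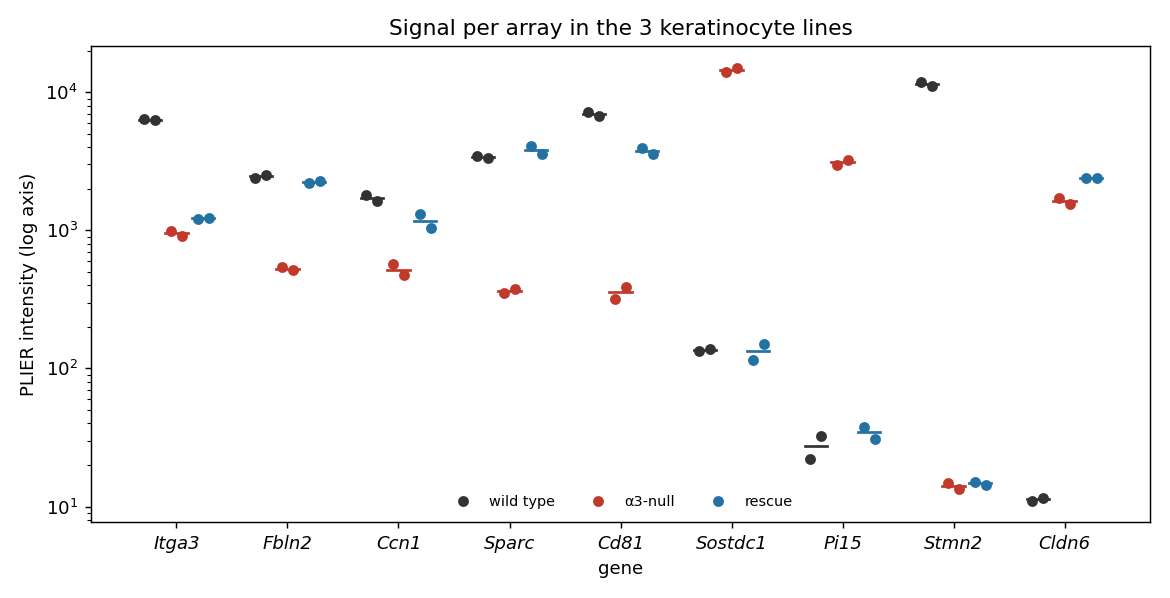
PLIER intensity (log axis) of 9 genes on each of the 6 arrays, with points for arrays, coloured by line, and a bar for the mean of 2 arrays. Fbln2, Ccn1, Sparc and Cd81 were lower and Sostdc1 and Pi15 higher in the null line than in both other lines, while Stmn2 and Cldn6 differed between the wild-type line and the other 2 lines.

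The comparison of the null with the wild-type line asked which transcripts differ when α3 is absent. Among the called members of the fixed lists, most differentiation, inflammatory, p53 target and matrix protease genes were lower in the null line, and most interferon-response, cell-cycle, cell junction and glutathione genes higher. Many members of each list were not called, and no list passed with an estimated correlation (lowest limma camera adjusted p = 0.478). That setting rests on 3 residual degrees of freedom, here and below, so its failures do not show that correlated genes made the calls. The largest rises included Sostdc1, a secreted BMP and Wnt antagonist, from 136 ± 2.70 to 14538 ± 767 (log2 difference 6.58), Pi15, a secreted CAP-family protein, from 27.2 ± 7.26 to 3116 ± 185 (6.19), the tight-junction gene Cldn6 from 11.3 ± 0.291 to 1630 ± 103 (5.92), and the transcription factor genes Hoxa11 (6.20) and Sox2 (4.67). The largest falls included those of Stmn2, a microtubule regulator, from 11398 ± 523 to 14.1 ± 1.09 (log2 difference -8.57), Slc16a3, a lactate transporter, from 9199 ± 585 to 55.2 ± 3.16 (-7.02), the epithelial cytokine Tslp from 3813 ± 574 to 25.4 ± 14.2 (-6.57), the neutrophil chemokine Cxcl1 from 2600 ± 36.1 to 16.1 ± 2.88 (-6.35), and the matrix glycoprotein Tnc from 2076 ± 155 to 41.1 ± 4.25 (-5.20). Other rises with log2 differences from 4.36 to 6.38 were those of Gpx2, Apobec3, Gsta3, Pir and Cxcl2. Other falls, from -5.25 to -5.07, were those of Slc6a14, Cd74, Ptgr1, Ociad2 and H2-Aa.

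Among 36 measured keratinocyte differentiation genes, 15 fell, 3 rose and 18 did not pass (18 and 4 adjusted over the list alone). The skin protease gene Asprv1 fell from 4097 ± 174 to 329 ± 8.02, the kallikrein genes Klk8 and Klk7 by log2 differences of -3.43 and -2.77, and Sprr1a, a cornified envelope precursor, from 6374 ± 324 to 1675 ± 1.89. The list passed limma's camera test (adjusted p = 2.27e-04), with adjusted p = 0.478 with an estimated correlation. Of 35 inflammatory genes, 15 fell and 4 rose (17 and 5 adjusted over the list alone), with Cxcl14 down from 2706 ± 192 to 149 ± 5.43 and Cxcl2 up from 48.2 ± 11.3 to 1292 ± 115. Its limma camera adjusted p was 4.42e-04, with adjusted p = 0.478 with an estimated correlation. Of 25 p53 target genes, 12 fell and 0 rose (14 and 2 adjusted over the list alone), led by Trp53inp1 (1341 ± 14.6 to 582 ± 20.5), Pmaip1 (-1.29), Eda2r (-1.18) and Btg2 (-1.01). Here limma's camera gave an adjusted p of 5.81e-04, and adjusted p = 0.478 with an estimated correlation.

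Of 34 matrix proteases, 13 fell and 3 rose (15 and 5 adjusted over the list alone), among them Adamts4, an aggrecanase, from 402 ± 31.9 to 93.7 ± 1.89 and the stromelysin gene Mmp3 from 198 ± 65.3 to 20.4 ± 0.125. This list had a limma camera adjusted p of 0.00481, and adjusted p = 0.478 with an estimated correlation. Its call was also lost with the filter at the median cluster (limma camera adjusted p = 0.160). Of 32 interstitial matrix genes, 5 fell and 1 rose, both over all clusters and adjusted over the list alone, with the short-chain collagen gene Col8a1 down by -5.05 and Thbs2, which encodes a thrombospondin, up by 2.91. In limma camera this list had an adjusted p of 0.0112, against adjusted p = 0.478 with an estimated correlation. The call was also lost with quantile normalization (limma camera adjusted p = 0.0542) and with the filter at the median cluster (0.119). The list of 30 basement membrane and hemidesmosome genes did not pass (limma camera adjusted p = 0.0568). In it 8 fell and 4 rose (9 and 4 adjusted over the list alone). Sparc fell from 3405 ± 79.1 to 364 ± 16.3, Fbln1 by -1.13 and Col4a1 by -1.11. Lists that passed by a narrow margin were hypoxia and glycolysis genes (9 of 26 fell and 3 rose; 11 and 4 adjusted over the list alone; limma camera adjusted p = 0.0463), YAP and TAZ targets (7 of 20 fell and 1 rose; 8 and 2 adjusted over the list alone; 0.0483) and Wnt signalling genes (4 of 33 fell and 2 rose; 5 and 2 adjusted over the list alone; 0.0364). With an estimated correlation their adjusted p was 0.478, 0.478 and 0.533, and each of these 3 calls was also lost under several other settings.

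Of 35 interferon-response genes, 15 rose and 1 fell in the null line (16 and 2 adjusted over the list alone), such as Rsad2, an antiviral enzyme gene, from 261 ± 3.45 to 624 ± 20.8 and Ifit2 from 64.8 ± 5.32 to 254 ± 25.8. The limma camera test of the list gave an adjusted p of 2.27e-04, and adjusted p = 0.481 with an estimated correlation. Of 37 cell-cycle genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with the mitotic kinesin genes Kif23 and Kif11 up by 0.64 and 0.60 and the replication helicase gene Mcm3 up by 0.59, while Ccne2 fell by 0.53. For these genes limma camera gave an adjusted p of 0.00788, and adjusted p = 0.481 with an estimated correlation. Among 35 epithelial junction genes 11 rose and 1, the plakophilin gene Pkp2, fell from 478 ± 13.0 to 77.6 ± 10.7 (14 and 1 adjusted over the list alone). Junction genes had a limma camera adjusted p of 0.0112, and adjusted p = 0.478 with an estimated correlation. Of 21 glutathione and NRF2 genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone), including Gsta3 (19.8 ± 2.80 to 1672 ± 105) and Gclc, a subunit of the enzyme that starts glutathione synthesis (821 ± 59.9 to 2316 ± 94.9), with Cbr1 down by -1.41. As a list they had an adjusted p of 0.0117 in limma camera, and adjusted p = 0.481 with an estimated correlation.

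Among the integrin genes, Itgb1, which encodes the partner of α3, rose from 4014 ± 138 to 7633 ± 13.7, Itga2 fell from 797 ± 88.1 to 93.3 ± 10.8 and Itgb5 fell by 0.93; 4 of 20 integrin genes rose and 4 fell, both over all clusters and adjusted over the list alone. Hox genes also went both ways, with 5 of 32 up and 5 down (6 and 6 adjusted over the list alone). Hoxa10 rose from 46.2 ± 11.1 to 449 ± 6.45, Hoxa9 from 231 ± 3.30 to 1116 ± 41.7 and Hoxb13 from 76.0 ± 5.49 to 415 ± 85.9. Among 16 immune-cell markers 4 fell and 0 rose, both over all clusters and adjusted over the list alone. Its limma camera adjusted p was 0.0140, with adjusted p = 0.478 with an estimated correlation. These were Coro1a, the MHC class II genes H2-Aa and H2-Ab1, and the invariant chain gene Cd74 (3145 ± 4.26 to 68.2 ± 9.28). Interferon-γ also induces H2-Aa, H2-Ab1 and Cd74 in keratinocytes. Of 26 fibroblast and mesenchymal markers 3 fell and 0 rose, namely Vim from 1070 ± 184 to 142 ± 7.66, Cdh2 by -1.02 and Twist1 by -0.97. Of 15 endothelial markers 1 fell (Flt1, -1.56), and of 13 melanocyte markers 1 rose (Gpnmb, 2.89); these 3 lists of markers did not pass the camera test, and their counts were the same when adjusted over each list alone.

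Over all 23332 transcript clusters, limma called 3578 at an adjusted p under 0.05, 1982 higher and 1596 lower in the null line, of which 634 differed by 2-fold or more (206 higher and 428 lower). All 3578 had non-overlapping groups, as did 56.3% of all clusters, where chance alone gives 33.3% (55.6% for rescue against null and 57.6% for rescue against wild type). The share of higher calls was 55.4%, against 53.2% after quantile normalization, 68.1% after median centring and 45.8% to 54.5% with an array left out. The lines came from different mice, so the comparison holds any other difference between these lines, and 1174 to 3524 clusters were called when an array was left out.

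The rescue line was then compared with the null line it came from, to ask what changed once human α3 was put back. Among the called members of the fixed lists, most inflammatory, p53 target, matrix protease and protease inhibitor genes were higher in the rescue line, and most interferon-response, cell-cycle, junction, basal keratinocyte and differentiation genes lower. Many members of each list were not called, and no list passed with an estimated correlation (lowest limma camera adjusted p = 0.521). The largest rises were in Mctp1, a calcium-binding membrane protein, from 24.4 ± 3.17 to 1096 ± 84.5 (log2 difference 4.78), the TNF receptor family gene Tnfrsf26 from 175 ± 14.0 to 4144 ± 492 (4.44), and Lcn2, an iron-siderophore binding protein, to 1830 ± 254 (4.26). They were followed by Speer3, Glipr2, Neurl3, Tnip3, Plscr2, Gatm and Arhgdib, at 4.19 to 3.54. Sostdc1 fell to 133 ± 24.9 (log2 difference -6.62) and Pi15 to 34.4 ± 4.65 (-5.96). Akip1, which encodes an A-kinase interacting protein, fell from 1016 ± 135 to 1.15 ± 0.288 (-5.91), and Slc25a13, a mitochondrial aspartate-glutamate carrier gene, from 1241 ± 84.5 to 10.5 ± 0.636 (-5.57). The desmosomal cadherin gene Dsc3 fell from 4210 ± 235 to 582 ± 51.2, and Igf2bp3, Pacs1, Slc50a1, Rcbtb2 and Tspan15 fell by log2 differences of -3.60 to -2.97.

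Of 35 inflammatory genes, 17 rose and 3 fell in the rescue line (19 and 3 adjusted over the list alone). The nitric oxide synthase gene Nos2 rose from 313 ± 25.5 to 1549 ± 124, the calprotectin gene S100a8 from 81.5 ± 8.08 to 895 ± 93.9 and the interleukin-1 family gene Il1f6 from 46.4 ± 12.4 to 375 ± 46.6. In limma camera this list had an adjusted p of 3.19e-05, against adjusted p = 0.641 with an estimated correlation. Of 25 p53 targets, 12 rose and 0 fell (15 and 1 adjusted over the list alone), with Trp53inp1 at 1652 ± 48.6, Eda2r at 1762 ± 5.10 and the death receptor gene Fas up from 95.7 ± 3.33 to 331 ± 33.1. The limma camera test of the list gave an adjusted p of 1.08e-04, and adjusted p = 0.641 with an estimated correlation. Of 23 protease inhibitors, 8 rose and 0 fell (11 and 1 adjusted over the list alone), among them Slpi from 375 ± 89.8 to 1722 ± 83.7 and Serpinb2 by 0.93. For these genes limma camera gave an adjusted p of 0.00185, and adjusted p = 0.710 with an estimated correlation. Of 34 matrix proteases, 11 rose and 0 fell (15 and 2 adjusted over the list alone), including Mmp3 to 156 ± 0.870, Mmp13 by 1.66 and Adamts4 to 190 ± 2.51. As a list they had an adjusted p of 0.00642 in limma camera, and adjusted p = 0.590 with an estimated correlation. That call was also lost with the filter at the median cluster (limma camera adjusted p = 0.144).

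Of 35 interferon-response genes, 18 fell and 0 rose in the rescue line (20 and 1 adjusted over the list alone), with Rsad2 at 318 ± 4.98, Ifit2 at 79.0 ± 4.62 and Stat2, a mediator of interferon signalling, down from 807 ± 29.4 to 402 ± 3.67. Its limma camera adjusted p was 8.77e-07, with adjusted p = 0.675 with an estimated correlation. Of 37 cell-cycle genes, 14 fell and 1 rose (19 and 2 adjusted over the list alone), such as Mcm5 by -0.85, Kif11 by -0.55 and the topoisomerase gene Top2a by -0.54. In limma camera this list had an adjusted p of 3.23e-04, against adjusted p = 0.675 with an estimated correlation. Basal keratinocyte genes fell in 8 and rose in 1 of 17 cases, both over all clusters and adjusted over the list alone; Dsg3 fell by 0.57 and the hemidesmosome gene Col17a1 by 0.67, while the aquaporin gene Aqp3 rose from 248 ± 38.3 to 952 ± 27.6. The limma camera test of the list gave an adjusted p of 0.00330, and adjusted p = 0.521 with an estimated correlation. Among 35 junction genes 11 fell and 4 rose (14 and 5 adjusted over the list alone), with Cldn3 up from 299 ± 18.7 to 2030 ± 175. For these genes limma camera gave an adjusted p of 0.00418, and adjusted p = 0.521 with an estimated correlation. Of 36 differentiation genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone), with Sprr1a at 309 ± 33.1 and Asprv1 at 132 ± 10.7. As a list they had an adjusted p of 0.00185 in limma camera, and adjusted p = 0.521 with an estimated correlation. Itgb1 fell to 5687 ± 272 and Itga2 rose to 350 ± 28.7. No immune-cell marker of 16 was called. Of 26 fibroblast and mesenchymal markers 2 rose (Cdh2, 1.41, and Twist1, 1.00) and 1 fell (Acta2, -0.60), with the same counts adjusted over the list alone.

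In this comparison limma called 3585 clusters at an adjusted p under 0.05, 2274 higher and 1311 lower in the rescue line, of which 544 differed by 2-fold or more (412 higher and 132 lower). Higher calls made up 63.4% as deposited, 49.9% after quantile normalization and 40.9% after median centring, which lowered all differences by a shift of -0.12 on the log2 scale, so the balance between small rises and falls rests on the scaling. Without an array, 1304 to 2689 clusters were called.

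**Figure D2:**
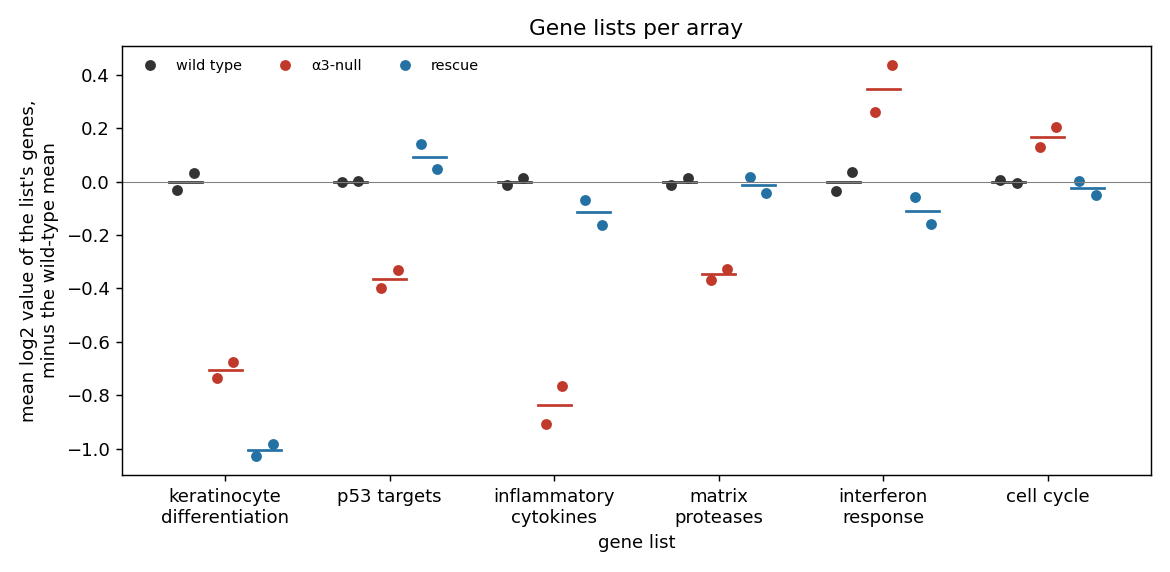
Mean log2 value of the measured genes of 6 lists on each of the 6 arrays, minus the mean of the wild-type arrays, with points for arrays, coloured by line, and a bar for the mean of 2 arrays. Differentiation genes averaged -0.71 in the null and -1.01 in the rescue line, while the other 5 lists lay farther from wild type in the null line than in the rescue line. These 6 lists are a selection from those that passed in null minus wild type. Of the lists not shown, hypoxia genes averaged -0.51 and -0.57, interstitial matrix genes -0.43 and -0.56, and immune-cell markers -1.04 and -1.01 in null and rescue. The rest averaged 0.78 and 0.61 (glutathione), 0.37 and 0.21 (junctions), -0.30 and -0.23 (YAP and TAZ), and -0.19 and -0.19 (Wnt).

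The rescue line was also compared with the wild-type line, to see what still differed after α3 was put back. Many of the strongest differences between null and wild type persisted. Stmn2 was at 14.7 ± 0.408, Slc16a3 at 51.3 ± 3.82, Cxcl1 at 11.6 ± 5.60 and Tnc at 31.1 ± 0.0461 in the rescue line, with log2 differences from wild type of -8.54 to -5.47, and Cldn6 at 2401 ± 17.3, Apobec3 at 2298 ± 157 and Hoxa11 at 1011 ± 22.5, with differences of 5.64 to 6.47. Other genes far above wild type were Cldn3, Pir, Gsta3, Mctp1, Cxcl2, Acap1 and Slc22a4 (4.65 to 6.11), and others far below were Akip1, Slc25a13, Tslp, Pdpn, H2-Ab1 and Cd74 (-6.23 to -5.29). Of these, Mctp1, Akip1 and Slc25a13 had changed between null and rescue, as described above, so their differences did not persist from the null line. Cldn3, higher than wild type in both other lines, also rose from null to rescue, so only part of its difference persisted from the null line. Of 36 differentiation genes, 19 were lower and 0 higher (22 and 2 adjusted over the list alone). The limma camera adjusted p of this list was 9.08e-11, and adjusted p = 0.184 with an estimated correlation. Interstitial matrix genes were lower in 6 and higher in 0 of 32 cases, both over all clusters and adjusted over the list alone, including Vcan and Fn1. Its limma camera adjusted p was 9.48e-05, with adjusted p = 0.642 with an estimated correlation. Hypoxia and glycolysis genes were lower in 11 and higher in 4 of 26 (14 and 5 adjusted over the list alone), such as the oxygen sensor gene Egln3, at 25.5 ± 2.80 against 876 ± 36.1. Their limma camera adjusted p was 0.0212, and adjusted p = 0.642 with an estimated correlation. Glutathione and NRF2 genes were higher in 8 and lower in 2 of 21 (10 and 2 adjusted over the list alone), with the cystine transporter gene Slc7a11 at 4824 ± 260 against 2117 ± 56.3. In limma camera this list had an adjusted p of 0.0303, against adjusted p = 0.642 with an estimated correlation. The call was also lost in 5 of 18 other settings. Among other cell-type markers, 4 of 26 fibroblast and mesenchymal markers were lower and 2 higher, including Vim (-2.59) and Cdh11 (-0.75) below and S100a4 (0.55) above wild type. Of 16 immune-cell markers 4 were lower and 0 higher, and neither count changed when adjusted over the list alone. Neither list passed (limma camera adjusted p = 0.165 and 0.105). In this comparison limma called 3599 clusters, 2420 higher and 1179 lower, of which 740 differed by 2-fold or more. The share of higher calls was 67.2%, against 53.5% after quantile normalization and 60% after median centring, and 1088 to 2819 clusters were called when an array was left out.

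The 3 comparisons were then joined, to find transcripts that the rescue moved back toward wild type and those that differed from wild type in both other lines. In 1532 clusters the null line differed from wild type and the rescue moved the level back (713 higher and 819 lower in the null line), and in 1194 of them (77.9%) rescue and wild type were not called different. The count was 506 to 1216 with an array left out and 805 without the variance trend. Higher in the null line and lower in both others were Sostdc1, Pi15, Thbs2 (76.1 ± 3.81, 677 ± 72.4 and 88.2 ± 3.42 in wild type, null and rescue), Gpnmb, Gpx2, the metallothionein gene Mt4 (998 ± 75.2, 5425 ± 178 and 1119 ± 166), Rcbtb2, Npepl1, Plcb1 and Rps4l. Lower in the null line were Sparc, a matricellular protein gene (3405 ± 79.1, 364 ± 16.3 and 3822 ± 321), the tetraspanin gene Cd81, whose product binds integrin complexes (6984 ± 326, 355 ± 50.4 and 3744 ± 270), the creatine synthesis gene Gatm, the DNA repair gene Mgmt (582 ± 7.13, 56.6 ± 16.3 and 541 ± 68.9), Arhgdib, Susd4, S100a8, Glipr2, Dixdc1 and the adhesion molecule gene Mcam (1396 ± 38.0, 163 ± 9.15 and 1240 ± 102). Both differences reached 2-fold in 173 clusters, of which 138 were lower in the null line. For the 1194 restored clusters without a call between rescue and wild type, the missing call does not show a full return. In the simulated data, log2 changes of 0.5 and 1 in null minus wild type were recovered in only 16% and 66% of changed clusters.

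In 1522 clusters both the null and the rescue line differed from wild type in the same direction (909 higher and 613 lower), with both differences 2-fold or more in 337. This count was 515 to 1067 with an array left out and 959 without the variance trend. They included Apobec3, Cldn6, Hoxa11, Gsta3, Pir, Cxcl2, Slc22a4, Gpx2, Sox2 and Cldn3 among those higher, and Stmn2, Slc16a3, Cxcl1, Tslp, Cd74, Tnc, Ptgr1, Col8a1, H2-Aa and Ociad2 among those lower. Gpx2 and Hoxa11 are among 188 clusters in both sets, since the rescue moved them only part of the way. Another 150 of the 1532 restored clusters were called past wild type in the rescue line, on the side opposite to the null line. In 1379 clusters the rescue line differed from both others (1032 higher and 347 lower), a count of 454 to 978 with an array left out and 814 without the variance trend. Comparisons that share arrays overlap by construction; 100 simulations without any effect gave 0 restored clusters in every run and a mean of 0.03 that were not restored. Without an effect almost no cluster is called, so these values do not measure how far shared arrays raise the overlap among real calls. Independent lists of the same lengths would share 111 higher and 156 lower clusters for the restored set, and 206 and 80.6 for the set not restored. Each line had only 2 arrays, so a split with 2 arrays on each side was not possible, and part of the overlap may come from the shared arrays. Across clusters, which are not independent replicates, the covariance of the log2 differences was -0.0754 for null minus wild type against rescue minus null (-0.0164 simulated) and 0.159 for the pair that shares wild type (0.0166 simulated), with r of -0.372 (-0.498 simulated) and 0.645 (0.502 simulated). For the pair that shares the rescue line the covariance was 0.0997 (0.0165 simulated) and r 0.469 (0.4998 simulated), so its covariance lay farther from the simulated value than that of the restored set.

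**Figure D3:**
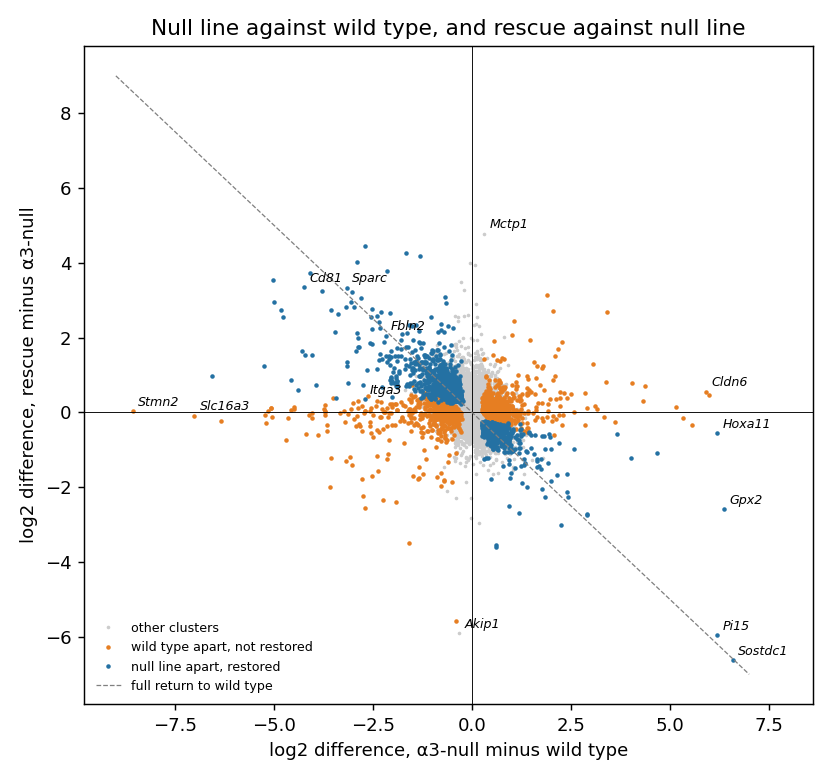
Log2 difference of each of 23332 transcript clusters between null and wild type (horizontal axis) and between rescue and null (vertical axis). Blue points are the 1532 clusters that the rescue moved back, orange points those called different from wild type in both other lines and not blue, grey points all others, and the dashed line marks a full return to the wild-type level.

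Genes that earlier work tied to α3β1 were followed as a list, partly chosen by the study on these samples, so its counts are not independent evidence. Fbln2, a basement membrane fibulin, was at 2454 ± 83.1 in wild type, 528 ± 15.9 in the null and 2241 ± 43.3 in the rescue line (log2 differences -2.18 and 2.05). The matricellular gene Ccn1 was likewise lowest in the null line, at 1713 ± 124, 519 ± 67.3 and 1177 ± 203, and so was Plau, the urokinase gene, at 5378 ± 153, 3789 ± 65.0 and 5764 ± 544. The gelatinase gene Mmp9, at 115 ± 10.4, 60.6 ± 10.5 and 111 ± 30.0, fell in the null line (limma adjusted p = 0.0461), and its difference between rescue and null did not pass (limma adjusted p = 0.0601). Ptgs2, the inducible cyclooxygenase gene, was at 3319 ± 179 and 3787 ± 135 in wild type and null and lower at 1504 ± 166 in the rescue line. Irs1, an insulin receptor substrate gene, rose from 77.3 ± 2.28 to 422 ± 30.9 in the null and further to 627 ± 47.5 in the rescue line. Bmp1 fell by 0.27 in the null line, Fst by 0.44 from null to rescue, and Ccn2 was lower in rescue than in wild type by a log2 difference of -0.76. Angptl4, Vegfa and Sema3a were not called in any comparison. Of the 12 measured genes, 5 fell and 1 rose between wild type and null (6 and 1 adjusted over the list alone), 4 rose and 2 fell between null and rescue (5 and 2), and 1 was higher and 2 lower in rescue than in wild type (2 and 4). The list did not pass in any comparison (limma camera adjusted p = 0.178, 0.513 and 0.225). Fbln2, Ccn1 and Ptgs2 kept these calls in every alternative setting, whereas the falls of Mmp9 and Bmp1 in the null line ended with median centring and in several other settings. The calls of Plau, Fst and Ccn2 and the second rise of Irs1 were each lost when some single array was left out.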

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

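No called result for a named gene or a list changed direction under any alternative, and all alternatives were fixed before the data were examined. The direction of the other called clusters was not compared between settings. Of 419 called results for named genes, 240 kept the call in every setting, and 18 of 26 list calls were kept in all settings but the estimated correlation. Most named genes were chosen for large differences or small adjusted p, so their share does not describe all calls. The 2-fold threshold alone ended 174 of these calls, and genes removed by a filter on dim clusters were not counted as lost. Without the variance trend, 63.3%, 62.3% and 65.2% of all calls were kept in null minus wild type, rescue minus null and rescue minus wild type. Arrays hold no detection p-values here, so signal over background could not be judged for dim genes; where an array is left out, the lone array of its line is assumed to vary like the others. Except where the setting itself makes fewer arrays or clusters, the cause of a change was not tested.

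Without the variance trend 2306 clusters were called in null minus wild type, 2277 in rescue minus null, 805 as restored and 959 as not restored. The 2-fold threshold left 634, 544, 740, 173 and 337 for the 3 comparisons, the restored set and the set not restored. A fit of only null and rescue arrays called 2343 clusters. Leaving out an array gave 1174 to 3524 calls in null minus wild type, 1304 to 2689 in rescue minus null, 1088 to 2819 in rescue minus wild type, 506 to 1216 restored and 515 to 1067 not restored clusters, with 9 to 14, 9 and 3 to 4 lists. For lists, the estimated correlation left 0 in each comparison (limma adjusted p from 0.184), and fry gave 27, 17 and 16. Beside the estimated correlation, 8 list calls were lost in some of 18 settings (the highest limma camera adjusted p in brackets). In null minus wild type these were hypoxia genes in 8 settings (0.0604), YAP and TAZ targets in 7 (0.0894), Wnt genes in 7 (0.116), interstitial matrix genes in 2 (0.119), matrix proteases in 1 (0.160) and glutathione genes in 1 (0.0525). They were matrix proteases in 1 (0.144) in rescue minus null and glutathione genes in 5 (0.195) in rescue minus wild type.

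The rise of Itga3 from null to rescue lost its call with quantile normalization (log2 difference 0.29, limma adjusted p = 0.0540), median centring (0.23, 0.0740), no variance trend (0.35, 0.0682) and the fit of only null and rescue arrays (0.35, 0.0623). It was 0.29 to 0.42 with an array left out, and lost the call in 5 of these 6 fits (limma adjusted p = 0.0610 to 0.101, against 0.0499 where it was kept). With replicate number as a block, 3102, 3124 and 3099 clusters were called, and replicate numbers showed no pairing (r of deviations -0.0232 to 0.0536).

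Among the named genes and the lists, only results that were not called changed sign. With quantile normalization these were Oca2 in null minus wild type (0.0068) and Kdm5d in rescue minus null (-0.054). With median centring they were Oca2 (0.0032) in null minus wild type, and Bmp1 (-0.016), H2-M2 (-0.064) and Kdm5d (-0.039) in rescue minus null. With an array left out, null minus wild type ranged from -0.19 to 0.0016 for Angptl4, -0.057 to 0.18 for H1f5, -0.45 to 0.16 for H2ac1, -0.027 to 0.094 for Sema3a and -0.33 to 0.062 for Slc45a2. Rescue minus null ranged from -0.043 to 0.15 for H2-M2, -0.092 to 0.65 for H2ac8 and -0.22 to 0.033 for Sema3a. Rescue minus wild type ranged from -0.11 to 0.025 for B2m, -0.36 to 0.0087 for H1f2, -0.31 to 0.18 for Mmp9 and -0.19 to 0.066 for Sema3a.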

Other observations

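In what follows, the ratio of the null and rescue lines' own clusters was chosen before the data were examined, and every test on neighbouring genes, including those beside Itga3, after the results were seen.

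Single genes of several lists that did not pass also differed between the lines. Krt19, a keratin of simple and stem-like epithelia, was at 5101 ± 489 in wild type, 869 ± 157 in the null and 5950 ± 433 in the rescue line (log2 differences -2.54 and 2.76), whereas the hyperproliferation keratin Krt16 fell in both steps, by -0.58 and -1.14. Of 11 stress and simple keratins, 4 fell and 1 rose between wild type and null, both over all clusters and adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.123). Of 8 histone genes 1 rose and 1 fell, also adjusted over the list alone (limma camera adjusted p = 0.783), the latter being the linker histone gene H1f1, which fell by 4.78 in the null line and rose by 2.56 in the rescue line. Of 41 growth and angiogenic factors 5 rose and 9 fell in the null line, also adjusted over the list alone (limma camera adjusted p = 0.285). The EGF receptor ligand Epgn fell by -2.25 and then by -2.34, Vegfd fell by -1.73 in the null line, and Vegfc fell by -1.03 and then rose by 2.56 in the rescue line. Of 25 lysosome and autophagy genes 2 rose and 4 fell (3 and 5 adjusted over the list alone; limma camera adjusted p = 0.467), with the protease gene Ctsz down by -3.67, and of 22 imprinted genes 3 rose and 6 fell, also adjusted over the list alone (limma camera adjusted p = 0.171), with Ndn down by -2.01.

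The Y-linked gene Kdm5d was at 10.1 ± 3.96 in wild type, 215 ± 5.89 in the null and 229 ± 0.631 in the rescue line, log2 differences of 3.16 and 3.24 from wild type. Eif2s3y, also Y-linked, was at 88.9 ± 3.82 in the rescue line, 1.51 above wild type, and was not called between null and wild type (0.22). These 2 genes were too few to test as a list.

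Clusters in which the null line stood apart from both others numbered 1532, and those in which the rescue line did numbered 1379, a ratio of 1.11. At the 2-fold threshold the rescue line stood apart more often (173 and 216, a ratio of 0.801). Without the variance trend the counts were 805 and 814 (0.989). In the other settings with all arrays the ratio was 1.06 to 1.44. The ratio was 0.859 to 1.51 with an array left out. A rule set in advance asked for 1.5 or more in every fit to rule out that any line would stand apart to this extent, and for 1 or less in every fit to keep that reading. Neither was met. Leaving out a null array lowered the ratio and leaving out a rescue array raised it, so the rule could hardly be met either way. With all arrays the ratio lay on both sides of 1 (0.801 to 1.44). The count of restored clusters alone therefore cannot tell α3 from other differences between the lines. Lines made by repeated transfection of the same null cells with and without α3 would separate them.

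Neighbouring genes shifted together in part of the genome. The windows counted below held 6.86% to 15.3% of the calls among the 8779 ordered genes. In them 52.5% to 54.2% of genes were called, against 25.4% to 29.3% elsewhere. They were chosen by their shift, which raises that share. The runs they formed reached 147 genes in null minus wild type (Mto1 to Nradd, 71 called lower and 6 higher). In rescue minus wild type they reached 208 (Cgas to Fyco1, 71 lower and 47 higher). Among 8779 genes in the order of assembly GRCm38.p6, r between neighbours was 0.0842 to 0.110 and 3.83% to 8.04% of genes lay in windows beyond the shuffled orders' 95th percentile; the strongest window of 25 had a median log2 difference of -0.67 between null and wild type (Irak1bp1 to Chst2) and 0.93 between rescue and wild type (Camsap3 to Arhgef7), relative to all genes. Shuffled orders reached 0.50 and 0.42, a p of 0.001, the smallest that 1000 shuffles can give, so chance order is excluded; in the second window only 2 of 25 genes shared a name stem with another, too few to set its median, so probes shared within families of like-named genes are excluded as its source. The window from Camsap3 to Arhgef7 was also the strongest between rescue and null, at 0.83 relative to all genes. Between null and wild type its median log2 difference was 0.079, with 15 genes up and 10 down. A gain or loss of a chromosome segment cannot be told from other causes. In new windows chosen on every other gene, 62.5% of the 24 genes between them moved in the window's direction for rescue against null (Timm44 to Smim19). The share was 75% for null against wild type and 70.8% for rescue against wild type. Each new window spanned 25 chosen genes and the 24 between them, a longer stretch than the strongest windows of 25. It could therefore reach past a shorter segment, which would lower the share. Both tests replaced, after their values were seen, earlier ones whose outcome was nearly fixed (the median with 1 gene per name stem, 0.978, which dropped only 1 gene, and the share of genes within the strongest window), and DNA copy number of the lines would settle whether segments were gained or lost.

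Genes beside Itga3 did not stand out between null and wild type. Of the 20 nearest measured genes 5% (1 gene) were called, where windows of 20 genes elsewhere had a median of 20% and a 95th percentile of 40%. Flanking DNA carried along with the targeted allele is excluded only as a source of excess calls among these 20 genes (5%). Some of them were dim, such as Chad at 35.0 and Hils1 at 32.1 in wild type, and others bright, such as Lrrc59 at 3967. The log2 scale understates changes of the dim ones. Genes farther from Itga3 were not tested in this way, so the test does not decide whether flanking DNA contributed to differences beyond these 20.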
